A study of Mus musculus with 22 samples.

How the data were processed

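RNA-seq was made from mouse bone marrow-derived macrophages of 2 genotypes under 4 treatments, in 22 libraries, with 2 libraries in each PBS group and 3 in each of the other 6 groups. The deposited table holds expected counts per gene, one column per library, which the authors made from 150 bp paired-end reads and deposited without normalization; 4.7% of values, in 1551 genes, are not whole. Per the submitters' processing notes, reads were trimmed or filtered with fastp 0.23.2 and the genome build was GRCm39. The aligner, the counting program, its gene annotation and whether it used strand are not given in the sources used here. Reads of near-identical gene copies and of overlapping or antisense genes may therefore have been split or merged, and values of such genes are uncertain. Per the labels' protocols the libraries came from a stranded mRNA kit of Illumina after 2 h with particles or PBS, whereas the series design text gives 30 min, an untreated control and a kit of another maker. The text follows the sample labels for the names of groups and leaves the time and the kit open.

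Expected counts were rounded to whole numbers. Gene identifiers were matched to a RefSeq table of the mouse for names only (17192 of 17243), and 25 symbols that a spreadsheet had turned into dates were restored from their identifiers; since that table is on another build, no coordinates are given. Total counts ran from 17805987 to 18794096 per library. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15, by group), which left 12293 genes holding 99.97% of counts. The common biological coefficient of variation, the spread between replicates beyond counting noise, was 4.4%. With so small a spread, small fold changes pass. As the labels give no origin for the replicates, this spread may be technical. Group values are TMM-scaled CPM, as mean and SD over libraries.

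Tests used edgeR 4.0.16 in R 4.3.3: a quasi-likelihood model with a coefficient for each of the 8 groups over all 22 libraries and no covariate, a two-sided test of each contrast, and Benjamini-Hochberg adjustment over genes at 0.05. All 22 libraries share a spread estimate because PBS groups of 2 libraries give little on their own. The 16 comparisons were each particle against PBS within each genotype, KO against WT within each treatment, the difference of the KO and WT responses to each particle, and the pairs of particles within WT. Log2 fold changes are given with their SE, and an adjusted p quoted without another name is from this model or from the set test of the list in the same sentence. Exact permutation of 3 against 3 libraries cannot go below 0.1, so single genes were not tested that way.

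Gene lists were fixed before the data were examined: 25 lists with 467 names, of which 24 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the lists in each comparison. Camera with a correlation estimated from the data and fry were alternatives. The size of the particle response was the median, over genes whose mean response of both genotypes passed and was at least 2-fold, of the KO response minus the WT response, with fry's directional p and its p for change in either direction, each adjusted over the 6 sets. The named genes were also fixed by rule before the data were examined: a panel of 14 genes, the 8 genes up and 8 down with the largest fold change among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of both groups (3 and 3 for comparisons other than WT responses and KO against WT), and up to 4 members of each list with the smallest p. Predicted and unnamed genes were left out. Some genes that the rule names are not reported here. Genes and lists singled out after their values were seen are said to be so.

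Alternatives, chosen before the data were examined, were RLE size factors, no filter on low counts, a fit to only the groups compared, the replicate number as a block, replicates 2 and 3 only, leaving out each of the 22 libraries, and DESeq2 1.42.0. Where leaving out a library leaves 1 PBS library in a genotype, that library is assumed to vary like the other groups. Removal of transcript length and GC trends per library was added after seeing the data. Whether replicate numbers pair libraries was checked by correlating same-numbered libraries' deviations from their group means. Between genotypes every pair was over 0.1 with hyphae (0.155 to 0.346) and with Zymd (0.114 to 0.152), while with yeast they ran from −0.267 to 0.248. This pairing comes from the data alone, as the labels give no origin for the numbers, and a block within hyphae and Zymd libraries was added for those 2 comparisons. Replicates were compared for duplicates by a chi-square test on genes with counts of at least 20, and all pairs differed by more than counting noise. The methods were tested on simulated data, with counts drawn for the 12293 tested genes from the real means, spreads and library sizes. In these data 200 genes were changed, and 12203 genes passed the filter. The draws held no deviation shared across a library, so the shares below do not cover an odd library. For KO against WT with hyphae 74% of genes changed 1.25-fold, 90% of those changed 1.5-fold and all changed 2-fold were recovered, with 9 false among 191 calls. For the difference of responses to hyphae the shares were 26%, 76% and 96%, with 5 false among 154 calls. In a simulated KO against WT comparison with PBS that held no change, edgeR made 0 calls.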

Results

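Messenger RNA was profiled in mouse bone marrow-derived macrophages, which had been grown from marrow for 7 days with M-CSF (20 ng/ml) and serum (10%). The 22 libraries fell into 8 groups, from 2 genotypes and 4 treatments. The genotypes were macrophages with floxed Tbk1 alleles and no Cre (labelled WT) and macrophages with the same alleles and Cre expressed from the Lyz2 locus (labelled KO). Tbk1 encodes a kinase that phosphorylates IRF3 downstream of nucleic acid sensors and Toll-like receptors, and the series title places it with the kinase SRC in macrophage defence against fungi. Cells received PBS, heat-killed hyphae of Candida albicans, the heat-killed yeast form of the same fungus, or particles that the labels call depleted zymosan (Zymd here), zymosan being a cell wall preparation of yeast. PBS groups held 2 libraries per genotype, replicates 2 and 3, and the other 6 groups held 3 each. Total counts per library ran from 17805987 to 18794096, and 12293 of 17243 genes in the table were tested. The sample labels give 2 h of treatment, while the series design text gives 30 min, so the time is open between these values. Nothing in the labels says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component of log2 CPM, the counts scaled to library size, held 59.4% of the variance over 8742 genes and parted the 4 PBS libraries from the 18 particle libraries.

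Tbk1 transcript was lower in every KO library than in every WT library. It measured between 218.5 and 233.7 CPM in the 11 WT libraries and between 54.07 and 62.58 CPM in the 11 KO libraries. With PBS the levels were 223 ± 3.42 CPM (SD, n = 2) in WT and 59.7 ± 1.03 CPM (SD, n = 2) in KO, a 3.74-fold difference. Tbk1 was 4.01-fold lower with hyphae, 3.78-fold lower with yeast and 3.71-fold lower with Zymd, at adjusted p between 3.88e-21 and 3.47e-24. The count covers the whole gene and does not show which exon was deleted, so a part of the signal can come from transcript of the remaining exons. Lyz2, the gene that carries the Cre insertion and encodes a lysozyme, stood at 8922 ± 286 CPM in WT and 10240 ± 1010 CPM in KO with PBS (SD, n = 2 each) and was not called in any of the 4 treatments (adjusted p = 0.0621 with PBS, 0.514 with hyphae, 0.83 with yeast and 0.652 with Zymd).

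**Figure D1:**
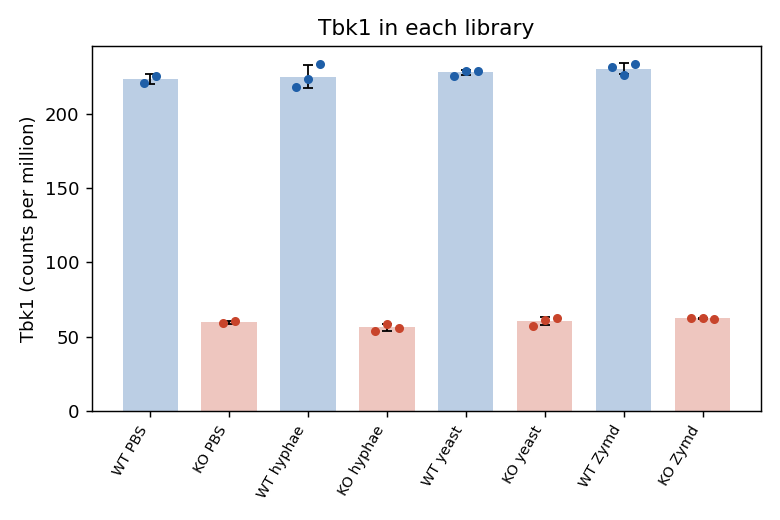
Tbk1 in CPM in the 8 groups, with bars at the group mean, error bars of 1 SD and a dot for each library. WT libraries lie between 218.5 and 233.7 CPM and KO libraries between 54.07 and 62.58 CPM.

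Which genes respond to hyphae was asked first in WT macrophages. Within the labelled time the cells raised early transcription factors, cytokines and chemokines. Egr1, a growth factor-inducible zinc finger transcription factor, went from 4.97 ± 0.734 CPM (SD, n = 2) with PBS to 233 ± 25.2 CPM (SD, n = 3), and Egr3, of the same family, rose 58.2-fold. Tnf, the pyrogenic cytokine released early by macrophages, went from 34.5 ± 7.56 to 706 ± 42.7 CPM, a log2 fold change of 4.36 ± 0.09 (SE, adjusted p = 3.68e-25). Il10, an anti-inflammatory cytokine, rose 32.8-fold from 0.651 ± 0.125 to 21.5 ± 1.3 CPM, while Cxcl3, a neutrophil attractant, rose 24.2-fold and Il1b 10-fold. Enc1 fell by 1.70 on the log2 scale (SE 0.05), from 174 ± 3.96 to 53.6 ± 1.43 CPM, and the cell death genes Bmf and Bbc3, which encode BH3-only proteins, were 2.91-fold and 2.34-fold lower. Of 4 other BH3-only genes, named after their values were seen, Pmaip1 (log2 fold change 1.18 ± 0.08) and Bcl2l11 (0.23 ± 0.04) were higher, while Bad (0.07, adjusted p = 0.574) and Bid (0.08, 0.519) were not called.

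Among the lists fixed before the data were examined, the immediate early and MAPK feedback list led the hyphae response, with 26 of 28 tested members up and 1, the phosphatase gene Dusp6, down (26 and 1 adjusted over the list alone). Of 22 NF-kB feedback genes and targets 21 rose (adjusted over the list alone, 21), among them Nfkbiz (13.7-fold) and Tnfaip3 (4.88-fold). Of 18 inflammatory cytokines 15 rose (16 adjusted over the list alone), including Tnfsf9 (19.4-fold) and Il1a (18-fold), and of 17 chemokines 14 rose (15), including Ccl4 (11.9-fold) and Ccl3 (8.43-fold). These 4 lists passed the set test at adjusted p = 3.41e-107, 9.27e-63, 6.86e-47 and 1.14e-34 in that order. Of 25 C-type lectin receptors and proximal signalling genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), with Clec4e, the receptor Mincle, up 9.12-fold, Malt1 up 2.28-fold and Src up 1.28-fold (adjusted p = 7.42e-06). Of 22 glycolysis and hypoxia genes 14 rose (17 adjusted over the list alone), such as the glucose transporter gene Slc2a1 (1.64-fold, list adjusted p = 4.74e-07), and of 22 cell death and inflammasome genes 9 rose (9), such as Nlrp3 (3.13-fold, 1.5e-05). Inducible antimicrobial and lipid-mediator effectors rose in 8 of 19 members (8 adjusted over the list alone, adjusted p = 4.35e-12), with Ptgs2, the inducible cyclooxygenase, up 24.3-fold and Ptx3 up 7.76-fold. NRF2 targets rose in 10 of 18 (10, 9.43e-11), with Hmox1, which degrades heme, up 2.58-fold.

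Cholesterol synthesis genes rose in 12 of 22 members with hyphae (14 up and 1 down adjusted over the list alone, adjusted p = 7.42e-06), with Insig1 up 2.6-fold, and this call was lost at adjusted p = 0.0839 with an estimated correlation. The same held for the endoplasmic reticulum stress list (8 of 17 up, 9 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.103 with an estimated correlation) and the TBK1 pathway list (7 of 20 up and 1 down, 7 and 1 adjusted over the list alone, 0.0487, and adjusted p = 0.0839 with an estimated correlation), in which Sqstm1 rose 2.27-fold. Interferon-stimulated genes went both ways, with 14 of 31 up and 3 down (14 up adjusted over the list alone), among them Rsad2, the antiviral protein viperin, at a log2 fold change of 0.54 ± 0.07 and Stat2 at −0.34 ± 0.05, and the list was not called (adjusted p = 0.228). In total 3820 genes changed with hyphae in WT, 2027 up and 1793 down, of which 341 changed at least 2-fold. The count was 2442 without WT PBS replicate 3.

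The yeast form of Candida raised cytokine, chemokine and early transcription factor genes in WT cells too. Tnf reached 1029 ± 52 CPM (SD, n = 3), a 29.9-fold rise (log2 fold change 4.90 ± 0.09, adjusted p = 4.38e-26), Il10 rose 49.9-fold to 32.8 ± 0.474 CPM and Il1b rose 15.3-fold to 212 ± 22.3 CPM. Egr3 rose 51.7-fold, Egr1 37-fold, Cxcl3 34-fold and Ptgs2 29.5-fold. Enc1 was 4.03-fold lower, the arrestin family gene Arrdc3 3.9-fold lower and Bmf 3.22-fold lower. Src rose 1.51-fold (adjusted p = 8.23e-09).

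By list, yeast raised 16 of 18 inflammatory cytokines (16 adjusted over the list alone, adjusted p = 1.49e-57), 14 of 17 chemokines (14, 3.86e-41), 21 of 22 NF-kB genes (21, 9.89e-79) and 26 of 28 immediate early genes with Dusp6 again down (26 and 1, 3.08e-90). C-type lectin and proximal signalling genes rose in 12 of 25 (12, 2.76e-08), with Clec4e up 11.8-fold, and antimicrobial and lipid-mediator effectors in 13 of 19 (15, 3.78e-17), with Acod1, which makes itaconate, up 6.77-fold. Glycolysis and hypoxia genes rose in 18 of 22 (18, 5.83e-07) and cell death and inflammasome genes in 11 of 22 (12, 5.83e-07). The TBK1 pathway list had 9 of 20 up and 1 down (9 and 1, adjusted p = 0.0123). Calls lost with an estimated correlation were NRF2 targets (10 of 18 up, adjusted p = 3.15e-07, then adjusted p = 0.0651 with an estimated correlation), cholesterol synthesis (14 of 22 up, 4.62e-06, then adjusted p = 0.0765 with an estimated correlation), endoplasmic reticulum stress (7 of 17 up, 0.0405, then adjusted p = 0.296 with an estimated correlation) and interferon-stimulated genes (18 of 31 up and 2 down, 20 up over the list alone, 0.00575, then adjusted p = 0.543 with an estimated correlation). Yeast changed 3731 genes, 2037 up and 1694 down, of which 374 at least 2-fold, and 2296 without WT PBS replicate 3.

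With Zymd, Egr3 rose 109-fold from 0.654 ± 0.419 CPM (SD, n = 2) to 71.5 ± 8.07 CPM (SD, n = 3), and Egr1 rose 35.2-fold. Tnf rose 12.5-fold to 430 ± 10.3 CPM (log2 fold change 3.64 ± 0.09, adjusted p = 1.53e-23), Il10 22-fold and Il1b 9.54-fold. Gdf15, a stress-induced cytokine of the TGF-beta family, rose 19.1-fold, and Rasd2, a small GTPase of the Ras family, rose 17.5-fold from 0.365 ± 0.0816 to 6.5 ± 0.566 CPM. Csf1, which encodes M-CSF, the growth factor of these cultures, rose 6.35-fold to 573 ± 28 CPM. Enc1 was 3.96-fold lower, Angptl4 3.77-fold lower and Abhd15 3.14-fold lower.

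In the Zymd response 13 of 18 inflammatory cytokines rose (14 adjusted over the list alone, adjusted p = 3.44e-38), as did 13 of 17 chemokines (13, 6.55e-39), 21 of 22 NF-kB genes (21, 1.44e-46), and 23 of 28 immediate early genes with Dusp6 down (23 and 1, 3.43e-81). Glycolysis and hypoxia genes rose in 19 of 22 (20, 1.92e-13), with the kinase genes Pfkfb3 and Hk2 up 2.26-fold and 2.22-fold. C-type lectin and proximal signalling genes rose in 11 of 25 (12, 3.4e-06), antimicrobial effectors in 8 of 19 (9, 1.07e-08), NRF2 targets in 10 of 18 (10, 5.3e-12), cell death genes in 8 of 22 (8, 0.000116) and TBK1 pathway genes in 8 of 20 with 3 down (0.0051). Cholesterol synthesis had 10 of 22 up and 1 down (0.00721, then adjusted p = 0.316 with an estimated correlation) and endoplasmic reticulum stress 8 of 17 up (0.00748, then adjusted p = 0.158 with an estimated correlation). Interferon-stimulated genes rose in 11 of 31 and fell in 2 (16 up over the list alone), Rsad2 rose 2.17-fold, and the list was not called (adjusted p = 0.0575). Zymd changed 3611 genes in WT, 1917 up and 1694 down, of which 405 at least 2-fold. The phagosome, LXR target, alternative activation, cell cycle and macrophage identity lists were not called in any of the 3 WT responses, nor were the neutrophil, dendritic cell, lymphocyte, mast cell, stromal and osteoclast marker lists. Median, mean and test did not share a sign for the dendritic cell and neutrophil lists with hyphae and yeast, for LXR targets with yeast and Zymd, for macrophage identity and mast cell markers with yeast, or for cell cycle, lymphocyte and stromal markers with Zymd.

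**Figure D2:**
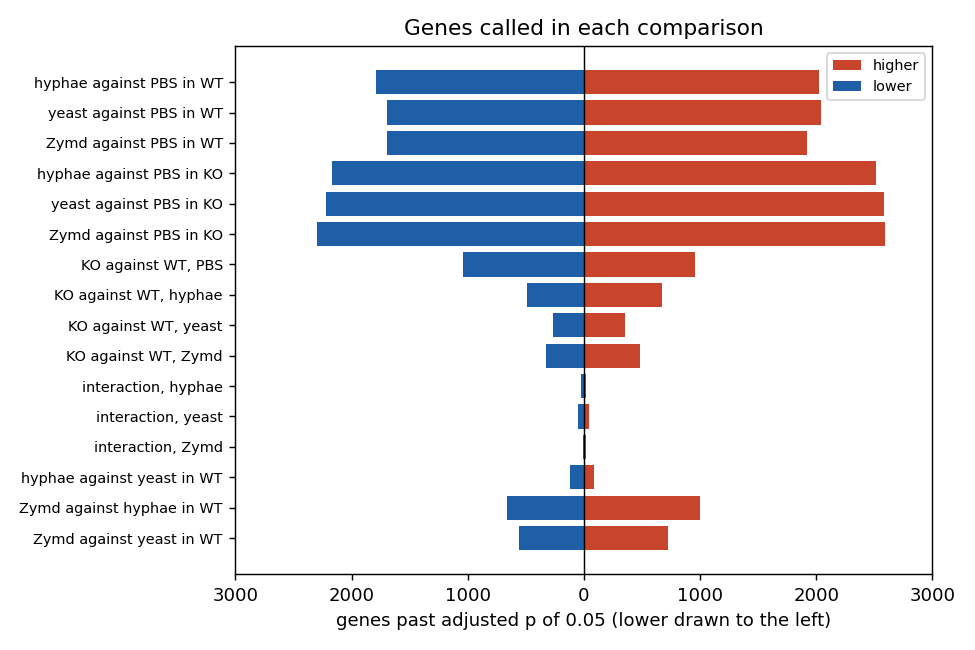
Genes called in each of the 16 comparisons at an adjusted p under 0.05, with genes higher to the right and lower to the left. Particle responses hold 3611 to 4891 genes, KO against WT 613 to 1991, and the differences of response 24 to 95.

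KO macrophages mounted a large response to each particle too. Tnf rose 16.2-fold with hyphae, 24-fold with yeast and 10.9-fold with Zymd, and Il10 rose 39.1-fold, 66.6-fold and 26-fold. Egr1 rose 52.4-fold, 37.6-fold and 37.6-fold in that order, and Enc1 fell by 1.65, 2.04 and 1.92 on the log2 scale, with SE 0.05 in each. Hyphae changed 4678 genes in KO (2513 up, 2165 down), yeast 4799 (2579 up, 2220 down) and Zymd 4891 (2593 up, 2298 down), against 2760, 2887 and 3088 without KO PBS replicate 3. Of the genes up in WT, 1577 were up in KO with hyphae, 1516 with yeast and 1576 with Zymd, where independent lists of those sizes would share 414.4, 427.4 and 404.4. Of those down in WT, 1224, 1194 and 1237 were down in KO, against 315.8, 305.9 and 316.7. The WT and KO comparisons share no libraries, but they share the filter, the scaling and the spread estimate and so are not fully independent.

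Each list called in WT with a particle was called in KO with that particle, except interferon-stimulated genes with yeast. Inflammatory cytokines rose in 15, 15 and 14 of 18 members with hyphae, yeast and Zymd, and chemokines in 12, 12 and 12 of 17. NF-kB genes rose in 21, 21 and 20 of 22 and immediate early genes in 26, 25 and 23 of 28, with 1 down in each. C-type lectin genes rose in 9, 11 and 12 of 25 (Itgam and Tyrobp were down with hyphae, and Tyrobp with Zymd). Glycolysis genes rose in 12, 13 and 14 of 22, NRF2 targets in 13, 11 and 10 of 18 (1 down with hyphae and 1 with Zymd), and cell death genes in 10, 10 and 11 of 22. The TBK1 pathway list was called with all 3 particles (9 of 20 up in each, with Ikbke, Irf7 and Tbkbp1 down with hyphae, Tbkbp1 with yeast and Mavs with Zymd, and adjusted p = 0.0523 with an estimated correlation for hyphae). Antimicrobial effectors were called with all 3 as well (8, 7 and 6 of 19 up, with 1 down with yeast and 1 with Zymd, and adjusted p = 0.0688 with an estimated correlation for Zymd). Cholesterol synthesis rose in 12, 15 and 12 of 22 members and fell in 1, 1 and 3 (adjusted p = 0.0945, 0.0935 and 0.273 with an estimated correlation). Endoplasmic reticulum stress genes rose in 9, 10 and 13 of 17, with 1 down with yeast (adjusted p = 0.0945, 0.18 and 0.0688 with an estimated correlation). With yeast the cell cycle list rose in 16 of 26 members (adjusted p = 0.0316, and adjusted p = 0.307 with an estimated correlation). Interferon-stimulated genes were not called in KO, with 12 of 31 up and 6 down with hyphae (adjusted p = 0.591), 6 up and 4 down with yeast (0.924) and 12 up and 2 down with Zymd (0.3).

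How the genotypes differ without particles was read from KO against WT with PBS. Interferon-stimulated genes were higher in KO. Rsad2 stood at 303 ± 5.69 CPM in KO and 162 ± 11.9 CPM in WT (SD, n = 2 each; log2 fold change 0.91 ± 0.08, adjusted p = 3.68e-09), and Isg15, a ubiquitin-like modifier, at 103 ± 0.431 against 54.7 ± 6.51 CPM. Slfn4 was 2.43-fold and Ifit1bl1 2.91-fold higher. Cholesterol synthesis genes were lower in 13 of 22 members and cell cycle genes in 14 of 26. Scd2, a stearoyl-CoA desaturase, measured 215 ± 16.1 CPM in KO and 370 ± 2.16 CPM in WT (log2 fold change −0.78 ± 0.08, adjusted p = 7.47e-08), in the list of LXR targets, which had 4 of 12 higher and 2 lower and was not called (adjusted p = 0.896, median 0.13, mean −0.01). Top2a, the topoisomerase of dividing cells, measured 65 ± 3.38 against 95.8 ± 1.23 CPM. The proliferation marker gene Mki67 was lower, at a log2 fold change of −0.79 ± 0.11, as was the protease gene Mmp9 at −0.74 ± 0.13.

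With PBS 28 of 31 interferon-stimulated genes were higher in KO (29 adjusted over the list alone, median log2 fold change 0.37, adjusted p = 4.06e-43), including Oasl1 (1.06 ± 0.09) and Ifit3 (0.89 ± 0.08). Cholesterol synthesis was lower in 13 of 22 (14, and 1 higher, adjusted over the list alone, median −0.33, adjusted p = 2e-10), with Cyp51 at 35.3 ± 2.06 CPM in KO and 50.4 ± 3.74 CPM in WT. Cell cycle genes were lower in 14 of 26 (15, median −0.37, 9.52e-13), with Ccna2 at −0.55 ± 0.08. Immediate early genes were higher in 11 of 28 and lower in 4 (11 and 5 adjusted over the list alone), with Dusp1 at 0.60 ± 0.05 and Jund at −0.42 ± 0.06, and NF-kB genes were higher in 8 of 22 (10). Both lists were called (0.00222 and 0.00316) and both calls were lost, each at adjusted p = 0.383 with an estimated correlation. Beside these groups, the neutrophil and lymphocyte marker lists passed the set test, and neither call was kept with an estimated correlation. Their members need not be particular to those cells, so this does not show that other cells were present. Neutrophil markers were higher in 2 of 9 (adjusted p = 0.0471, and adjusted p = 0.383 with an estimated correlation), among them Ly6c2 at 0.68 ± 0.15, which was not called without KO PBS replicate 3 (adjusted p = 0.0895). Lymphocyte markers were higher in 3 of 9 (0.0202, and adjusted p = 0.305 with an estimated correlation), among them Cd4 at 0.63 ± 0.15, which was not called without WT PBS replicate 2 (adjusted p = 0.055). Inflammatory cytokines (3 up and 1 down of 18, adjusted p = 0.282) and chemokines (3 up of 17, 0.0596) were not called, though Ccl5 was higher (0.88 ± 0.10, adjusted p = 9.59e-07). In all, 952 genes were higher and 1039 lower in KO with PBS, 1991 together, 44 of them at least 2-fold. That number was 582 without KO PBS replicate 3, 915 without WT PBS replicate 2 and 916 without WT PBS replicate 3. Ifit, Slfn, Oasl and H2-Q genes have near-identical copies, between which the authors' counting could split reads, so their single values are uncertain.

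Under hyphae, KO cells made less of several inflammatory transcripts and more of others. Ccl9, a macrophage CC chemokine that acts on CCR1, stood at 85.2 ± 11.8 CPM in KO against 219 ± 29.4 CPM in WT (SD, n = 3 each; log2 fold change −1.36 ± 0.08, adjusted p = 1.6e-12), and the related chemokine gene Ccl6 at 327 ± 44 against 580 ± 70 CPM. Tnf was 1.31-fold lower, 538 ± 41.8 against 706 ± 42.7 CPM (adjusted p = 8.75e-05), while Il10 was 1.42-fold higher, 30.7 ± 2.21 against 21.5 ± 1.3 CPM (4.37e-06). Cd274, which encodes the checkpoint ligand PD-L1, was 1.86-fold higher at 514 ± 54.9 against 276 ± 14.5 CPM. Egr1 was 1.37-fold higher (adjusted p = 1.52e-05). Il1b was at −0.29 and not called (adjusted p = 0.098), but was called with the replicate number as a block over all libraries (−0.30 ± 0.08, adjusted p = 0.0128).

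All 31 interferon-stimulated genes tested were higher in KO with hyphae (31 adjusted over the list alone, median 0.37, adjusted p = 9.4e-64), among them Rsad2 (1.64-fold) and Ifit3 (0.79 ± 0.07). Immediate early genes were higher in 15 of 28 (18, adjusted p = 3.31e-17), such as Nr4a2 (0.50 ± 0.07) and Fos (0.40 ± 0.05). Cholesterol synthesis was lower in 14 of 22 (14, median −0.32, 2.69e-17), with Cyp51 at −0.41 ± 0.05, and cell cycle genes in 15 of 26 (24, median −0.29, 2.23e-16), with Top2a at −0.31 ± 0.05. Inflammatory cytokines were mixed, with Il10, Osm and Ebi3 higher and Tnf lower of 18, and were not called (0.185). Chemokines were not called either (4 higher, 5 lower of 17, 0.0597, median 0.05, mean −0.13), with Ccl2 at −0.50 ± 0.07 and Ccl5 at 0.44 ± 0.08. With the replicate number as a block within hyphae libraries the chemokine list was called lower (adjusted p = 0.000735, and adjusted p = 0.108 with an estimated correlation) and macrophage identity and stromal markers higher (0.036 each, and adjusted p = 0.347 and 0.304 with an estimated correlation). With a block over all libraries chemokines (0.0403) and osteoclast markers were called lower. The cell death, macrophage identity, mast cell and stromal lists were called higher (0.0405 each, as for osteoclast markers), with adjusted p from 0.15 to 0.333 with an estimated correlation. The pattern recognition genes Clec4e (−0.38 ± 0.05) and Ptx3 (−0.49 ± 0.07) and the adhesion gene Icam1 (−0.34 ± 0.05) were lower, and so was Zfyve21 at −1.10 ± 0.13. In all 670 genes were higher and 487 lower, 14 of these 1157 at least 2-fold. Without KO hyphae replicate 1 the count was 754, and without WT hyphae replicate 2 it was 764.

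With yeast the KO cells again had less Ccl9, at 95.5 ± 3.24 against 237 ± 2.81 CPM (SD, n = 3 each; log2 fold change −1.31 ± 0.08, adjusted p = 3.3e-12), and less Ccl6, at 316 ± 8.74 against 554 ± 1.78 CPM. Tnf was 1.29-fold lower, 797 ± 21.7 against 1029 ± 52 CPM (adjusted p = 0.000369), and Il10 1.59-fold higher, 52.3 ± 4.11 against 32.8 ± 0.474 CPM (1.01e-08). Cd274 was 1.71-fold higher. Hgsnat, a lysosomal acetyltransferase gene, was at −0.70 ± 0.06, Pgpep1 at −0.66 ± 0.06 and Mmp9 at −0.64. Saa3, an acute phase gene, was at −0.77 ± 0.20 (adjusted p = 0.021) and was not called without KO yeast replicate 2 (−0.62, adjusted p = 0.116) or without WT yeast replicate 3 (−0.38, adjusted p = 0.296).

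Of the fixed lists, 4 were called in KO against WT with yeast and kept with an estimated correlation. Interferon-stimulated genes were higher in 24 of 31 (29 adjusted over the list alone, median 0.25, adjusted p = 7.05e-42), such as Cmpk2 (0.61 ± 0.07), and immediate early genes in 12 of 28 (15, 1.79e-14), such as Fosb (0.57 ± 0.08). Cholesterol synthesis was lower in 15 of 22 (19, median −0.28, 6.73e-22), such as Acat2 (−0.52), and cell cycle genes in 4 of 26 (11, median −0.14, 1.18e-08), such as Rrm2 (−0.30). Chemokines had 3 higher and 4 lower of 17 (3 and 5 adjusted over the list alone, 0.00846, median 0, mean −0.14, and adjusted p = 0.275 with an estimated correlation), with Ccl2 at −0.37 ± 0.07. NF-kB genes had 1 higher and 1 lower of 22 (0.0149, and adjusted p = 0.465 with an estimated correlation). The TBK1 pathway list, which holds Tbk1 itself, was called lower (2 higher, 1 lower of 20, 0.0216, and adjusted p = 0.0759 with an estimated correlation) with a median of 0.08 and a mean of −0.04. Cell death genes had 4 of 22 higher (0.00846, and adjusted p = 0.0599 with an estimated correlation). Macrophage identity genes had 3 higher and 1 lower (0.0337, and adjusted p = 0.412 with an estimated correlation). Of markers of other cells, mast cell markers were higher in 2 of 5 (0.00263, and adjusted p = 0.0781 with an estimated correlation), and stromal markers passed the set test with 0 of 9 members called by edgeR over all genes, 4 at an unadjusted p under 0.05, 4 adjusted over the list alone and 2 called by DESeq2 (0.00263, and adjusted p = 0.11 with an estimated correlation). Inflammatory cytokines were not called (2 higher, 1 lower of 18, adjusted p = 0.24, median 0.06, mean −0.02). With yeast 350 genes were higher and 263 lower, 7 of the 613 at least 2-fold, and the count was 391 without WT yeast replicate 1.

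With Zymd, Ccl9 measured 97.6 ± 10.1 CPM in KO and 237 ± 15.1 CPM in WT (SD, n = 3 each; log2 fold change −1.28 ± 0.08, adjusted p = 6.48e-12), and Ccl6 346 ± 43.2 against 620 ± 34.8 CPM. Il1b was 1.54-fold lower, 86 ± 13 against 132 ± 8.56 CPM (adjusted p = 0.000436), and Il10 1.41-fold higher, 20.4 ± 0.419 against 14.5 ± 0.309 CPM. Tnf was 1.19-fold lower, 362 ± 5.53 against 430 ± 10.3 CPM (adjusted p = 0.0151), and was not called without KO Zymd replicate 1 (adjusted p = 0.0631), KO Zymd replicate 2 (0.0539) or WT Zymd replicate 3 (0.0762). Cd274 was 1.73-fold and Slfn4 2.15-fold higher. Mmp9 measured 24.6 ± 2.55 against 41 ± 3.83 CPM.

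The lists called with Zymd and kept with an estimated correlation were interferon-stimulated genes (30 of 31 higher, 31 adjusted over the list alone, median 0.36, adjusted p = 1.57e-77), immediate early genes (15 of 28 higher, 20, 1.81e-17), cholesterol synthesis (13 of 22 lower, 16, median −0.22, 1.48e-14), cell cycle (13 of 26 lower, 17, median −0.24, 7.54e-14), cell death (4 of 22 higher, 7, 0.000107) and osteoclast markers (3 of 8 lower, 0.000235). Zbp1, a nucleic acid sensor of the necroptosis pathway, was at 0.46 ± 0.06, Bcl2l11, which encodes BIM, at 0.27 ± 0.04, and the fusion gene Ocstamp at −0.66 ± 0.11. The osteoclast markers lower with Zymd were Ocstamp, Mmp9 and Itgb3. These 3 were also lower with PBS and hyphae, and Ocstamp and Mmp9 with yeast, where the list was not called (adjusted p = 0.193 with PBS, 0.0597 with hyphae and 0.0855 with yeast). NF-kB genes had 3 of 22 higher (8 and 1 down adjusted over the list alone, 0.000726, and adjusted p = 0.38 with an estimated correlation, or adjusted p = 0.028 with an estimated correlation and the replicate number as a block over all libraries), with Nfkbiz at 0.41 ± 0.07. Lymphocyte markers passed the set test with 0 of 9 called by edgeR over all genes, 4 at an unadjusted p under 0.05 and 0 by DESeq2 (0.0384, and adjusted p = 0.343 with an estimated correlation) and stromal markers with 2 of 9 higher (0.0086, and adjusted p = 0.21 with an estimated correlation). Inflammatory cytokines (2 higher, 3 lower, adjusted p = 0.264) and chemokines (6 higher, 3 lower, 0.338, median 0.14, mean −0.09) were not called, but chemokines were called lower with the replicate number as a block within Zymd libraries (0.0285, and adjusted p = 0.265 with an estimated correlation). With Zymd 483 genes were higher and 324 lower, 12 of the 807 at least 2-fold. The count was 510 without KO Zymd replicate 1, 500 without KO Zymd replicate 3, 481 without WT Zymd replicate 2 and 536 without WT Zymd replicate 3.

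**Figure D3:**
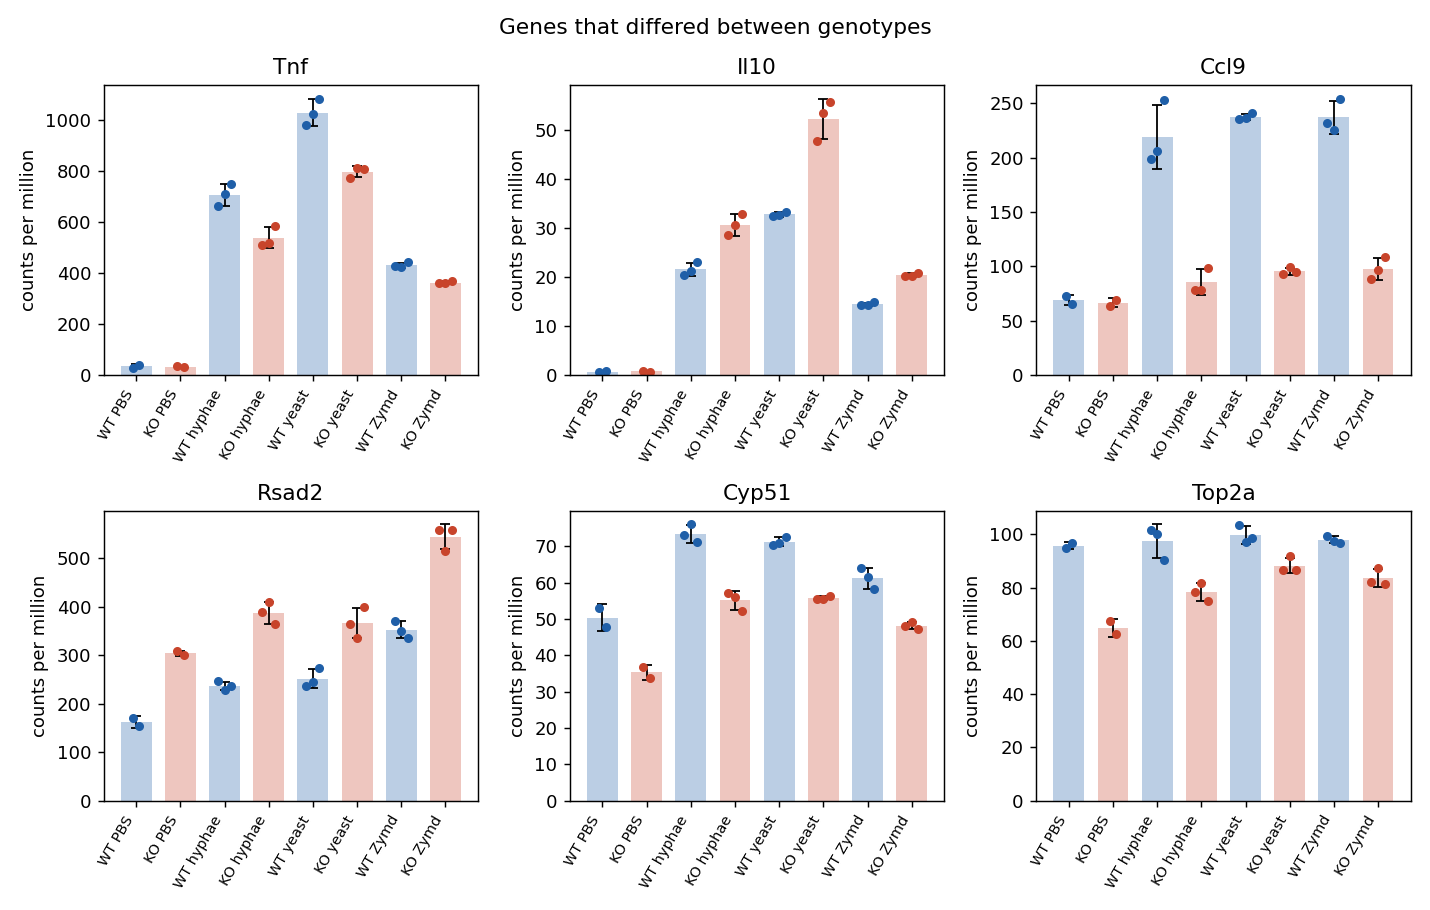
CPM of Tnf, Il10, Ccl9, Rsad2, Cyp51 and Top2a in each library of the 8 groups, a dot per library, WT beside KO. With hyphae Ccl9 averages 219 CPM in WT and 85.2 CPM in KO, and Rsad2 averages 236 CPM in WT and 387 CPM in KO.

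Across the 4 treatments 172 genes were higher in KO every time and 91 lower every time. Rsad2, Ifit3 and Cd274 were among the former and Tbk1, Mmp9, Hgsnat and Cyp51 among the latter. Hyphae and Zymd shared 336 higher and 186 lower genes, where independent lists would share 26.3 and 12.8, and PBS and hyphae shared 352 and 269, where 51.9 and 41.2 would be shared. No library is used in more than 1 of these 4 comparisons, but all share the filter, the scaling and the spread estimate. The labels do not say whether cells of a genotype came from the same animals or cultures across treatments. These overlaps are therefore not independent evidence of an effect of the deletion. Ccl9 and Ccl6 are not in the set of all 4: with PBS Ccl9 measured 66.4 ± 4.21 CPM in KO and 69 ± 4.73 CPM in WT (SD, n = 2 each). Ccl6 was not called lower with PBS. In the test of the response below, a difference was called for Ccl9 with each particle and for Ccl6 with none. Src and Clec7a, which encodes the beta-glucan receptor Dectin-1, were not called between genotypes in any treatment, with Src at adjusted p = 0.106, 0.439, 0.701 and 0.319 for PBS, hyphae, yeast and Zymd.

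**Figure D4:**
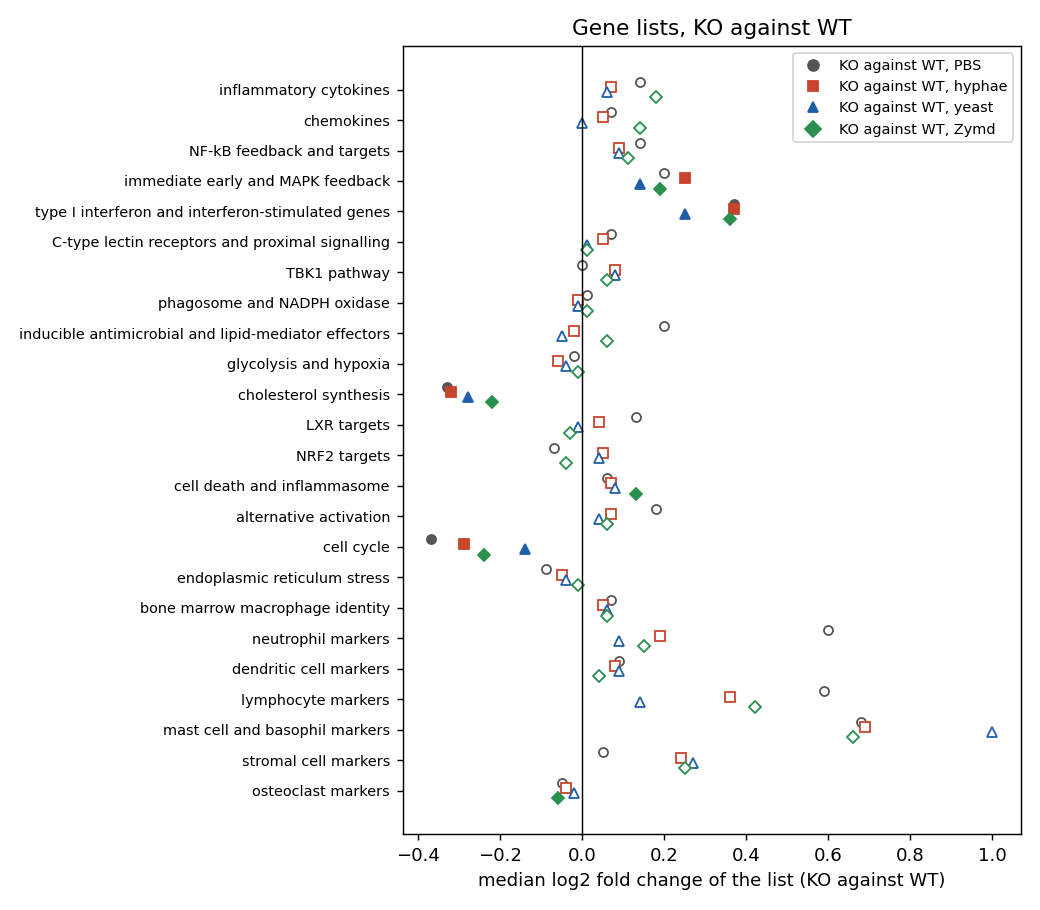
Median log2 fold change of KO against WT for the fixed lists under PBS, hyphae, yeast and Zymd, with points filled where the list's adjusted p is under 0.05 with an estimated correlation. Interferon-stimulated genes lie above 0 (medians 0.25 to 0.37) and cholesterol synthesis below 0 (−0.33 to −0.22) in all 4.

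Whether the response itself differed between genotypes was tested as the difference of the KO and WT responses. Ccl9 rose in WT from 69 ± 4.73 CPM (SD, n = 2) to 219 ± 29.4 CPM with hyphae (SD, n = 3), and its response was smaller in KO, with a log2 difference of −1.31 ± 0.13 for hyphae (SE, adjusted p = 1.73e-06), −1.26 ± 0.13 for yeast (3.68e-06) and −1.22 ± 0.13 for Zymd (6.66e-06). Lst1, a leukocyte transmembrane gene, responded lower in KO with yeast (−0.81 ± 0.11, adjusted p = 0.000297), going from 37.1 ± 0.485 to 26.7 ± 1.03 CPM in KO and from 22.2 ± 2.05 to 28 ± 1.92 CPM in WT. Tmsb10, an actin-sequestering thymosin, responded higher in KO with Zymd (1.07 ± 0.15, adjusted p = 0.00058), from 241 ± 50.7 CPM with PBS to 489 ± 9.62 CPM. With a PBS library left out these differences for Ccl9, Lst1 and Tmsb10 kept their direction and were still called. That of Tmsb10 ran from 0.87 without KO PBS replicate 3 to 1.30 without KO PBS replicate 2. The responses of Tnf and Il10 were not called as different for any particle. The 3 particle tests share the same 4 PBS libraries, so they are not independent of one another.

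The difference of response was called for 45 genes with hyphae (21 higher, 24 lower in KO), 95 with yeast (44 and 51) and 24 with Zymd (19 and 5). Without KO PBS replicate 3 the numbers were 4, 5 and 2, and without KO PBS replicate 2 they were 499, 789 and 717. Without WT PBS replicate 2 they were 6, 12 and 3, and without WT PBS replicate 3 they were 7, 16 and 11. Of the particle libraries with hyphae, leaving out KO replicate 1, 2 or 3 gave 17, 13 or 121 genes, and WT replicate 2 or 3 gave 26 or 14. For yeast the count was 55 without KO replicate 2 and 36 without WT replicate 3, and for Zymd it was 8, 8 and 15 without KO replicate 1, 2 or 3 and 11 and 9 without WT replicate 1 or 3. Libraries outside a comparison moved it too, as all libraries share the filter, the scaling and the spread estimate, which were not told apart. The hyphae count was 76 and 18 without KO yeast replicates 2 and 3, 22 and 24 without KO Zymd replicates 1 and 2, 21 and 22 without WT yeast replicates 1 and 2, and 16, 19 and 21 without WT Zymd replicates 1, 2 and 3, and the Zymd count was 38 without KO yeast replicate 2. The chemokine list was called lower in KO for all 3 particles (1, 2 and 1 of 17 members called, 4 in each adjusted over the list alone), and with yeast so were interferon-stimulated genes (3 of 31, 8), with the cell cycle list called higher (2 of 26, 3). All these calls were lost with an estimated correlation, at adjusted p = 0.388, 0.222 and 0.776 for chemokines, 0.444 for interferon-stimulated genes and 0.222 for cell cycle, each p with an estimated correlation.

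The size of the whole response was compared over genes chosen by their mean response in both genotypes. The 320 genes induced at least 2-fold by hyphae had a median log2 fold change of 1.52 in WT and 1.49 in KO, and the median difference was −0.004. The 291 genes induced by yeast had a median difference of −0.046 and the 346 induced by Zymd one of 0.018. For repressed genes the medians were −0.054 with hyphae (44 genes), −0.032 with yeast (83 genes) and −0.022 with Zymd (71 genes). None of the 6 sets passed the directional test (fry, adjusted p = 0.915 for each). Each of the 6 medians took either sign depending on the library left out. In fits with a library left out fry's directional p was not adjusted over the 6 sets. Without that adjustment genes repressed by Zymd passed without KO Zymd replicate 3 (−0.137), and further such cases are given below. In the test for change in either direction the induced sets passed, at adjusted p = 0.00122, 0.000459 and 0.00164 for hyphae, yeast and Zymd, as did the genes repressed by Zymd (0.000259), while those repressed by hyphae (0.202) and yeast (0.221) did not.

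How the particles differ was tested directly within WT. No dose of the particles is given here, so their kind and their amount cannot be told apart in any comparison between particles. Yeast gave more inflammatory transcript than hyphae: Tnf was 1.46-fold lower with hyphae (log2 fold change −0.54 ± 0.06, adjusted p = 3.85e-06), Il10 1.52-fold lower and Il1a 1.59-fold lower. Hyphae gave more Arl4d, an ARF-like GTPase, at 7.67 ± 1.27 CPM against 2.87 ± 0.889 CPM with yeast (SD, n = 3 each), and more Hspa1b, an inducible heat shock gene, at 63.1 ± 7.68 against 33.1 ± 2.98 CPM. Src was lower with hyphae (−0.24 ± 0.05, adjusted p = 0.0153), and this was not called without WT hyphae replicate 1 (adjusted p = 0.0563), 2 (0.0521) or 3 (0.0618) or WT yeast replicate 1 (0.0917) or 2 (0.0574). Inflammatory cytokines were lower with hyphae in 6 of 18 and higher in 1 (9 and 2 adjusted over the list alone, adjusted p = 4.22e-16), chemokines lower in 4 of 17 (8, 1.51e-08), such as Ccl4 (−0.55 ± 0.07), NF-kB genes in 7 of 22 (15, 3.8e-18), such as Nfkbid (−0.35 ± 0.05), and C-type lectin genes in 3 of 25 (3, 5.04e-05), such as Clec4e (−0.37 ± 0.05). Calls lost with an estimated correlation were immediate early genes (8 higher, 1 lower, adjusted p = 0.202 with an estimated correlation), interferon-stimulated genes (3 lower, adjusted p = 0.244 with an estimated correlation), antimicrobial effectors (4 lower, adjusted p = 0.061 with an estimated correlation), NRF2 targets (4 higher, adjusted p = 0.226 with an estimated correlation), endoplasmic reticulum stress (3 higher, adjusted p = 0.226 with an estimated correlation), cell death (2 lower, adjusted p = 0.0831 with an estimated correlation) and stromal markers (0 of 9 called by edgeR or DESeq2, 1 at an unadjusted p under 0.05, adjusted p = 0.268 with an estimated correlation). Hyphae and yeast differed in 211 genes, 88 higher and 123 lower with hyphae, 3 of them at least 2-fold. The count was 127 without WT hyphae replicate 1, 139 without WT hyphae replicate 2, 136 without WT yeast replicate 1 and 134 without WT yeast replicate 2.

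Zymd stood further from both forms of Candida. Against hyphae, Rasd2 was 3.06-fold higher with Zymd, Tnfsf8, the CD30 ligand gene, 2.51-fold, Hivep3 2.4-fold and Csf1 2.33-fold (573 ± 28 against 247 ± 8.91 CPM, SD, n = 3 each, adjusted p = 1.1e-13), while Tnf was 1.64-fold and Nfkbiz 2.29-fold lower. Against yeast, Rasd2 was 4.98-fold and Adprhl1 4.19-fold higher, and Socs3, a feedback inhibitor of cytokine receptors, 3.35-fold lower at 39.1 ± 0.684 against 131 ± 10.8 CPM. Tnf was 2.39-fold and Il10 2.27-fold lower with Zymd than with yeast (adjusted p = 1.28e-14 and 2.77e-13). Glycolysis genes were higher with Zymd in 5 of 22 members against hyphae (7 adjusted over the list alone, adjusted p = 3.25e-06) and in 5 against yeast (6, 7.57e-07), with Hk2 at 0.62 ± 0.05 and 0.61 ± 0.05. Against yeast, inflammatory cytokines were lower in 9 of 18 and higher in 2 (9 and 3 adjusted over the list alone, 4.42e-15) and NF-kB genes lower in 13 of 22 (15 and 1 higher, 1.02e-22). Against hyphae these lists were called as well, with cytokines lower in 8 and higher in 2 (adjusted p = 0.305 with an estimated correlation), NF-kB genes lower in 7 and higher in 3, immediate early genes lower in 12 and higher in 6, chemokines higher in 4 and osteoclast markers higher in 4 of 8 (each adjusted p = 0.305 with an estimated correlation). Cholesterol synthesis was lower in 7 of 22 and higher in 1 against hyphae (adjusted p = 0.335 with an estimated correlation) and lower in 6 and higher in 1 against yeast (adjusted p = 0.247 with an estimated correlation). Antimicrobial effectors were lower in 5 of 19 against hyphae (adjusted p = 0.623 with an estimated correlation) and in 8 against yeast (adjusted p = 0.0587 with an estimated correlation), and NRF2 targets higher in 5 against yeast (adjusted p = 0.247 with an estimated correlation). Zymd differed from hyphae in 1659 genes (999 higher, 660 lower) and from yeast in 1287 (725 higher, 562 lower), the latter 820 without WT yeast replicate 3.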

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

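A test of the difference between the genotypes' responses to a particle picked out the genes and lists of the next 2 paragraphs and the Ccl9 response, while the interferon-stimulated genes higher in KO and Ccl6 are results of KO against WT. The tests of length and GC trends on the differing responses and the simulation of an odd library were chosen only after the result was seen, and the counts without KO PBS replicate 3 had been seen before its test was set up.

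The response differed between genotypes for 45 genes with hyphae, 95 with yeast and 24 with Zymd. With hyphae the response was higher in KO for Bcl7a (1.17), H1f2 (1.02), Tmsb10 (0.84) and Mki67 (0.62) and lower for Ccl9 (−1.31), Lst1 (−0.70), Rps21 (−0.69) and Clec4e (−0.45), as log2 differences. With yeast it was higher for Ddias (1.10), Cntln (0.85), Tmsb10 (0.84), Mki67 (0.67) and Top2a (0.38), and lower for Ccl9 (−1.26), Nod2 (−0.88), Lst1 (−0.81), Ccl5 (−0.57), Isg15 (−0.56), Bst2 (−0.52) and Oasl1 (−0.48). With Zymd it was higher for Tmsb10 (1.07), Basp1 (0.63), Cul3 (0.63), Bnip3 (0.55) and Egr2 (0.37) and lower for Ccl9 (−1.22) and H2-M2 (−0.32). Without KO PBS replicate 3 all these calls were lost, at adjusted p from 0.0973 (Isg15) to 0.494 (H2-M2), except those of Ccl9 with each particle, Lst1 with hyphae and yeast, and Tmsb10 with Zymd. Mki67 with hyphae shrank to 0.41 without that library. Lst1 with hyphae was lost without WT PBS replicate 3 (−0.61). It was also lost with only the groups compared (adjusted p = 0.051) and with replicates 2 and 3 only (0.0647). Other calls were lost with only the groups compared, among them Bcl7a (adjusted p = 0.102) and Clec4e (0.195) with hyphae and Oasl1 with yeast (0.11). Of the 27 calls, 18 were lost without WT PBS replicate 2 (adjusted p 0.0571 to 0.291) and 16 without WT PBS replicate 3 (0.0532 to 0.252). Each hyphae, yeast or Zymd library except WT hyphae replicate 1 and KO hyphae replicate 3 ended between 2 and 8 of them, at adjusted p from 0.0504 (WT hyphae replicate 2) to 0.141 (WT Zymd replicate 1). Several of the differing genes already differed with PBS, where KO had less Mki67, Top2a and Ddias and more Isg15, Oasl1 and Ccl5 than WT.

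Gene lists whose response differed were chemokines with hyphae (adjusted p = 3.02e-05), yeast (1.01e-05) and Zymd (0.00142), all lower in KO, and with yeast interferon-stimulated genes (3.69e-08), antimicrobial effectors (0.00842) and lymphocyte markers (0.0477), lower, and cell cycle (0.000115) and NRF2 targets (0.0477), higher. None of these 8 calls of fixed lists was kept with an estimated correlation (camera, 0 of 72 list tests called and 4 at an unadjusted p under 0.05), where adjusted p ran from 0.222 to 0.776. No member of the antimicrobial or lymphocyte lists was called by edgeR or DESeq2, with 6 and 3 at an unadjusted p under 0.05. Of the lists made after the values were seen, MHC class I and peptide loading differed with hyphae (2.21e-07), yeast (3.18e-11) and Zymd (8.11e-06), lower in KO, guanylate-binding and immunity-related GTPases with yeast (0.0192), lower, and heat shock genes with hyphae (0.0384) and Zymd (0.00864), higher. With an estimated correlation MHC class I with yeast stayed just under the threshold (adjusted p = 0.0447), but in only 6 of 22 fits with a library left out (up to 0.109 without KO PBS replicate 3), and the other 5 calls were lost (adjusted p 0.149 to 0.406).

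A single odd library, KO PBS replicate 3, was weighed first for the differing responses, and over the 164 calls the median ratio of the difference without it to that with it was 0.85, against 1.15 without KO PBS replicate 2 and 1.01 and 0.99 without WT PBS replicates 2 and 3. Only 11 calls were made without it, and the KO PBS libraries differed most of all replicate pairs (chi-square over its degrees of freedom 8.41, next 7.12). A pair does not show which of its 2 libraries is odd, and KO PBS replicate 2 was not simulated as the odd one. A ratio over 0.5 had been set in advance as evidence against KO PBS replicate 3 as the cause, but calls need libraries that lie close together. Simulated data in which it alone deviated gave a ratio of 0.76 over the 6 calls of 5 simulations. At 2 times that deviation the ratio was 0.78 over 3 calls, so the ratio decides nothing. So few calls, next to 164 in the real data, argue against that library alone making them all. Yet the simulated spread came from the real fit, which already held its deviation and can make calls rarer. The library therefore stays open for the calls that were not made without it. Length and GC trends are argued against as the whole cause, since 121 of 164 calls stayed with the trends removed, but Rps21 with hyphae (−0.53, adjusted p = 0.07), Cntln with yeast (0.70, 0.0537) and Oasl1 with yeast (−0.39, 0.0778) were lost as their differences shrank. A difference between the cultures or animals of the genotypes stays open and was not tested.

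Interferon-stimulated genes higher in KO were the second pattern, opposite to the textbook role of TBK1 as an activator of interferon transcription. Reads shared between near-identical copies could make families such as Ifit move as a block, yet the 16 members without such copies had a median log2 fold change of 0.37 against 0.31 for the other 15, and all were above 0. Length and GC trends are argued against too, as 113 of 113 calls of list members higher in KO stayed with the trends removed. That macrophages without Tbk1 hold a higher resting interferon tone may account for the pattern and is a hypothesis that no test here decides, and a difference between the animals or cultures of the genotypes, and an effect of Cre itself, for which no Cre-only group is analysed here, stay open and untested.

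Ccl9 and Ccl6 lower in KO with particles were the third pattern. If their reads had gone to other CC chemokines, these would gain what was lost, but 10 other CC chemokines together gained 14.3% of the 393.7 CPM that Ccl9 and Ccl6 lost on average. Length and GC trends are argued against, since 6 of the 6 calls stayed with the trends removed. A difference of response between genotypes was called for Ccl9 with each particle but not for Ccl6, so a smaller response is shown for Ccl9 alone. Ccl9 rose with particles in WT from 69 to between 219 and 237 CPM, next to 85.2 to 97.6 CPM in KO. Whether this comes from the loss of Tbk1 was not tested, and a difference between the animals or cultures, including a variant near these genes, stays open and was not tested.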

How the results depend on the processing

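Removal of length and GC trends and the replicate block within hyphae and Zymd were the alternatives chosen after the data were seen; the first left all 16 counts within 1.5 times. Of 9141 fits of named genes under alternatives 8938 kept their direction and side of the threshold, 203 fell short of it and 0 turned. Many of these fits left out a library outside the comparison. Il1b with hyphae, which gained a call with the block over all libraries, is not among them, so gained calls are not fully counted. DESeq2 gave no adjusted p for 12 named gene results, among them Efcc1 and Hic1. Of 616 fits of counts, lists and sizes with a library left out, 533 kept theirs. Depth was alike in all libraries; the 2 PBS libraries per genotype limit KO against WT with PBS and every difference of response. Unless fewer libraries or genes explain it, the cause was not tested.

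With only the groups compared, KO against WT gave 898 genes with PBS, 282 with yeast and 1427 with Zymd, and the differences of response 2, 25 and 57 (hyphae, yeast, Zymd). With replicates 2 and 3 only, which leaves fewer libraries, KO against WT gave 414, 263 and 310, the differences 6, 28 and 3, hyphae against yeast 63, Zymd against hyphae 771 and Zymd against yeast 799. Without a low-count filter the differences were 289, 403 and 235, and hyphae against yeast 397. DESeq2 gave differences of 115, 179 and 82. Lists called with an estimated correlation numbered 17 for KO against WT, 0 for the differences (camera, 4 at an unadjusted p under 0.05) and 8 between particles; fry called 2 for the differences.

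With the replicate number as a block the differences of response were 110, 179 and 51. Same-numbered libraries correlated over 0.1 in 29 of 71 pairs (−0.267 to 0.346) with a median of 0.078, against −0.047 for different numbers, and 15 of 22 libraries correlated best with their own number. Deviations from a group mean cancel within the group, so the value for different numbers is tied to the other and is no separate reference. By the bound of 0.1 for each of at least 3 pairs, the numbers pair the genotypes with hyphae and with Zymd. They do not with yeast or between particles in WT. Comparisons with a PBS group hold 2 pairs, so this bound could not call them paired. Both pairs were over 0.1 for hyphae against PBS in KO (0.183 and 0.231) and for Zymd against PBS in WT (0.137 and 0.146). No pair was in the other comparisons with PBS. For KO against WT with hyphae and with Zymd the block within those libraries gave 1172 and 831 genes. Of these, 1090 and 772 were among the 1157 and 807 without it. Apart from the list calls and Il1b with hyphae given above, it or the block over all libraries changed no other call of a named gene or fixed list in these 2 comparisons.

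Response sizes near 0 changed sign: hyphae-induced 0.001 (RLE), 0.005 (only groups compared), 0.004 (block) and 0.001 (replicates 2 and 3); hyphae-repressed 0.043 (replicates 2 and 3) and 0.356 (chosen in WT); yeast-repressed 0.012 (no filter), 0.017 (replicates 2 and 3) and 0.249 (chosen in WT); Zymd-induced −0.021 (4-fold) and −0.036 (chosen in WT); Zymd-repressed 0.022 (block), 0.008 (replicates 2 and 3) and 0.271 (chosen in WT). Choosing genes by the WT response brings WT noise in by construction.

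Leaving out each library gave, lowest to highest: hyphae against PBS in WT 2442 to 3994 genes, yeast 2296 to 3902; in KO 2760 to 4837, 2887 to 4829 and 3088 to 5033; KO against WT 582 to 2414 (PBS), 754 to 1309, 391 to 713 and 481 to 901; differences 4 to 499, 5 to 789 and 2 to 717; hyphae against yeast 127 to 250, Zymd against yeast 820 to 1445; list calls for the differences 5 to 11. Response sizes ran from −0.074 to 0.092 and −0.227 to 0.146 (hyphae, induced and repressed), −0.145 to 0.006 and −0.117 to 0.179 (yeast), −0.054 to 0.114 and −0.137 to 0.092 (Zymd). Repressed genes passed with hyphae without KO PBS replicate 2 (−0.187), and with Zymd without it (−0.095) or without KO Zymd replicate 3 (−0.137).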

Other observations

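The lists in this part, and the genes named from them, were chosen only after the values were seen, and they share members with the fixed lists. Their p-values, here and above, are adjusted over these later lists alone. As the lists came from these same values, the p-values describe them and are no independent evidence, nor are they comparable with those of the fixed lists. The way the test near the engineered loci was read was also set after its count was seen.

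Heat shock and chaperone genes rose with every particle in WT, 13, 11 and 12 of 14 tested members with hyphae, yeast and Zymd (adjusted p = 0.00142, 0.00874 and 0.011 with an estimated correlation). Hspa1b, an inducible chaperone of the HSP70 family, rose by 4.11 ± 0.18 on the log2 scale with hyphae, from 3.65 ± 0.595 CPM (SD, n = 2) to 63.1 ± 7.68 CPM (SD, n = 3), and by 3.18 with yeast. Dnajb1 rose by 0.94 ± 0.07 with hyphae and Hsph1 by 0.35 ± 0.05. With hyphae 3 of the 14 were higher than with yeast, at doses not given here, Hspa1a (0.92), Hspa1b (0.93) and Dnajb1 (0.35). The list passed (adjusted p = 0.019 with an estimated correlation).

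Antigen presentation genes went with the interferon-stimulated genes in KO. MHC class I and peptide loading genes were higher in KO in 14 of 16 members with PBS, 9 with hyphae, 8 with yeast and 11 with Zymd (adjusted p = 0.00185, 0.00691, 0.0103 and 0.00161 with an estimated correlation), with the peptide transporter gene Tap1 at 0.52 ± 0.06 and H2-K1 at 0.52 ± 0.06 with PBS. The response of this list to yeast was lower in KO than in WT (4 of 16 members called, median difference −0.24, adjusted p = 3.18e-11, and adjusted p = 0.0447 with an estimated correlation). The last call was kept without KO hyphae replicate 1, KO yeast replicate 1, WT hyphae replicate 2 or 3, WT yeast replicate 1 or WT Zymd replicate 1 and was lost without any 1 of the other 16 libraries, at adjusted p up to 0.109 without KO PBS replicate 3. Without that library 0 members were called by edgeR (6 at an unadjusted p under 0.05) and the median was −0.15, without KO PBS replicate 2 they were 10 and −0.32, and without WT PBS replicates 2 and 3 or WT yeast replicate 3 the members called were 2, 1 and 2. Guanylate-binding and immunity-related GTPases, which attack microbes inside vacuoles, were higher in 12, 14, 10 and 14 of 14 (adjusted p = 0.00475, 0.00255, 0.00461 and 0.00022 with an estimated correlation), with Gbp6 at 0.55 ± 0.07 with hyphae. Fatty acid synthesis and desaturation genes were lower in 5, 4, 3 and 6 of 15 (adjusted p = 0.0111, 0.0078, 0.00665 and 0.00161 with an estimated correlation), beside the lower cholesterol synthesis genes. Members lower with PBS were Fads2, a desaturase of polyunsaturated fatty acids, at −0.70 ± 0.07 and Scd2, already given above, at −0.78 ± 0.08. These gene families hold near-identical copies, so single values are uncertain. The pro-apoptotic BH3-only list was not called in any comparison, with 2 of 6 members up and 2 down in each WT response.

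A hypothesis tied to the crossing scheme is that DNA from another strain, carried with the Lyz2 Cre allele, may have changed genes beside it. Both genotypes have the floxed Tbk1 alleles, so DNA carried with those alleles may be shared. Lyz2 and Tbk1 lie on the same chromosome, however, so DNA between and around them could still differ between the genotypes, which was not tested. The count takes neighbours of both genes together, and those of Lyz2 were not tested apart. Of 38 tested genes within 50 neighbours on either side of Lyz2 or Tbk1, 0 were called in the same direction in all 4 KO against WT comparisons by edgeR (1 at an unadjusted p under 0.05 in each). A count of 0 allows up to 9.3% (exact, 95% confidence), while 262 of 12253 other genes were called (2.14%, one-sided Fisher's exact p = 1). A share no higher than elsewhere had been set in advance as evidence against the hypothesis, but with 38 genes a share several times higher could have given 0 as well, so this stays open.

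Other splits of the 6 libraries of a comparison number 10 with the real one, too few for a share under 0.05; in each case only 1, the real one, gave as many genes. For KO against WT the real and highest other counts were 1157 and 1 with hyphae, 613 and 32 with yeast, and 807 and 0 with Zymd. With hyphae and Zymd, where the replicate numbers pair the genotypes, the 3 other splits that part all 3 pairs gave at most 0 genes (edgeR, up to 561 and 363 at an unadjusted p under 0.05), and the 6 that part 1 pair at most 1 and 0 (up to 1151 and 580). Between particles in WT they were 211 and 0 for hyphae against yeast, 1659 and 0 for Zymd against hyphae, and 1287 and 0 for Zymd against yeast. At an unadjusted p under 0.05 in edgeR the highest other splits gave 580 (Zymd, KO against WT), 1300, 726 and 835 genes where the adjusted count was 0.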
